A study of Arabidopsis thaliana with 30 samples.

How the data were processed

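Transcript levels were measured in the above-ground parts of soil-grown Arabidopsis thaliana of 3 weeks, kept in days of 16 h light and 8 h dark. The plants were axe1-5, a mutant of the histone deacetylase gene HDA6, and DR5, its parental line in the Columbia background. RNA came from plants at day 0 or after 6, 9, 12 or 15 days without water. Untreated plants were sampled only at day 0, so a change from day 0 also holds any effect of age and of harvest date. Each of the 10 groups has 3 independent biological replicates, so 30 arrays were used, each hybridised with 1 dye (Cy3).

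The scanner files hold 1 line per spot. Each spot's processed intensity was background-subtracted and spatially detrended by Agilent Feature Extraction 9.1.3.1, per the file headers. Low intensities were replaced by surrogate values and arrays were not scaled to one another, per the file headers. The intensity of the spot's pixels and of the local background, and flags for spots well above background, saturated or uneven, come from the same step, per the file headers. The authors also deposited a table of log2 values, and a test on the numbers showed each column to be the log2 of the processed intensity minus a constant that sets its 75th percentile to 0. That table served only as an alternative to the scanner files. The genome build behind the probes is not given in the sources used here.

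Each array has 39102 spots, of which 37685 are not controls. Between 56.5% and 67.7% of these were well above background and 0 were saturated. The 37478 probes include 26236 named for 1 locus, covering 25665 loci. Of these loci, 25449 matched the annotation of assembly TAIR10.1, which was used only for symbols and for which genes neighbour each other, and 216 did not. The 8812 probes named for chromosome intervals and the 2430 for other transcripts were not used in the gene counts. The number of arrays limits the precision: there are 3 per group.

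The log2 of the processed intensity was computed, spots marked as uneven or as outliers were left out, replicate spots of a probe were averaged, and each array's 75th percentile over non-control probes was subtracted. A probe was kept when well above background on all 3 arrays of at least 1 group. A locus took its values from the probe with the highest mean signal, and 21032 loci were tested. In these, 1705 values were left out for outlier marks.

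The limma package 3.58.1 in R 4.3.3 fitted a mean for each of the 10 groups over all 30 arrays, and its moderated test (2-sided) was applied to 18 comparisons. These were axe1-5 against DR5 at each of the 5 times and in the mean over the 5 times, each drought day against day 0 in each line, and the drought response of axe1-5 minus that of DR5 at each of the 4 drought days. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Errors are standard errors of the fit unless marked SD, and n = 3 arrays per group throughout. The design allows no p under 0.1 in a permutation of 3 arrays against 3.

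Genes dim in one group have no reliable fold. Where 0 of a group's 3 arrays were well above background, the mean of the other group was set against the mean of the dim arrays, each taken no lower than the lowest signal well above background on that array, and the fold is given as "at least". Where 1 or 2 arrays were above background, the fitted fold is given with that number. Differences of responses have no bound, and the fitted value is printed also where a group was dim.

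The headers showed 8 slides, 3 scan days and 2 scan sessions. Every group has 1 array in session 1 and 2 in session 2. No slide holds both lines at the same day, so the lines can be compared within a session but not within a slide. A fit with slide as a block was therefore set beside the results.

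A set of 25 gene lists was written from general knowledge before the data were examined, along with the tests and most of the alternatives. They are HDA6 alone, the acetate pathway, hypoxia response, abscisic acid metabolism, abscisic acid phosphatases and transcription factors, dehydrin and late embryogenesis abundant genes, proline and raffinose metabolism, DREB transcription factors, photosynthesis, jasmonate, salicylic acid and defence, senescence, flowering time, floral organ markers, root markers, seed and embryo, other histone deacetylases, heat shock, reactive oxygen response, anthocyanin and flavonoid, expansins, cell cycle, aquaporins, auxin response and circadian clock. The acetate list comes from what is known of this study's own published work. Listed genes whose symbols did not match the annotation (PDC4, PRODH1, PRODH2, NAC092, HSP23.6, HSP17.6C, HSP17.8 and UGT75C1) were dropped. A further list of transposable element genes came from words in the probe descriptions, and several of its 8 measured members are not true transposons. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison.

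The genes named were set by a rule. In each family of comparisons, at the day with the most calls, these are HDA6 and the acetate list, the 5 largest rises and the 5 largest falls among called genes, and up to 4 called members of each list with the largest folds. Except for the difference of responses, the largest changes also had no overlap between the arrays of the groups compared. Exceptions are marked where they appear as chosen after their values were seen.

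The alternatives were quantile normalization, normexp background correction with an offset of 50, no filter on dim probes, the mean over probes of a gene, slide as a fixed or random block, scan day as a block, the replicate number as a block, the deposited table, a fit of the compared groups alone, and each replicate left out in turn. Added after the data were seen were scan session as a block, the fit without DR5 day 15 replicate 2, and the fit without the day 15 arrays. Medians and quantities for lists, splits and neighbours were computed with R and Python 3.11.15, and plots were drawn with matplotlib 3.10.9.

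The procedure was tested on simulated data with 21032 genes. For axe1-5 against DR5 at day 0 it recovered 64% of 100 genes changed 2-fold and 83% of 100 changed 4-fold, and called 6 unchanged genes. For the difference of responses at day 15 it recovered 40% and 81%, and called 12. A simulated list of 20 genes shifted by 0.5 was called by camera at an adjusted p = 3.8e-14, and 0 of the 25 other lists were. The simulated genes were independent of each other, with the same spread in every group and no slide effect. In the data the median SD of a group ran from 0.127 in DR5 at day 0 to 0.384 in DR5 at day 15. The simulation therefore does not show how the tests behave with correlated genes or unequal spread.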

Results

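The 30 arrays measured transcripts of 2 lines, axe1-5 and its parental line DR5, at day 0 and after 6, 9, 12 and 15 days without water, with 3 biological replicates per group. The 75th percentile of the signal lay between 961 and 1783 intensity units per array. Correlations between replicates of a group ran from 0.941 in DR5 at day 15 to 0.996. The first principal component held 60.5% of the variance and, within each line, ordered the arrays by days without water. The second held 10.7% and the third, which separated the lines, 8.71%. DR5 day 15 replicate 2 stood apart from its group on the first component, at 253.8 against 200.3 and 206.2, as did DR5 day 12 replicate 2, at 99.9 against 18.6 and 40.9. Arrays of session 1 and session 2 were both present in every group.

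**Figure D1:**
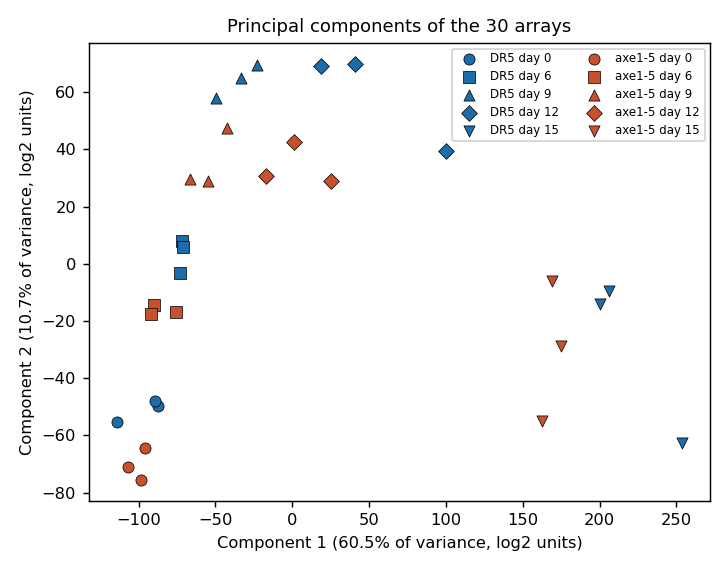
Principal components of the 30 arrays, with component 1 (60.5% of the variance) on the x axis and component 2 (10.7%) on the y axis, DR5 in blue, axe1-5 in orange and a marker for each day. Day 15 arrays lie at 162.3 or more on component 1, and DR5 day 15 replicate 2 lies farthest out, at 253.8.

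HDA6 (AT5G63110), the gene altered in axe1-5, was measured first. Its level relative to the array's 75th percentile was 0.14 ± 0.04 (SD, n = 3) in DR5 and -0.32 ± 0.09 in axe1-5 at day 0, a log2 difference of -0.46 ± 0.11 (limma adjusted p = 0.0207). At days 6, 9, 12 and 15 the difference was -0.34, -0.23, -0.16 and 0.03, and HDA6 was not called at any of them. HDA6 rose by 0.38 in DR5 and by 0.87 in axe1-5 at day 15. The place of the probe relative to the lesion in axe1-5 is not given in the sources used here, so the HDA6 level does not check the labels. The day 0 call was lost without DR5 day 0 replicate 1, 2 or 3 or axe1-5 day 0 replicate 1 or 3, with log2 differences from -0.47 to -0.41 and adjusted p from 0.0556 to 0.118. The HDA6 difference was -0.34 within session 1 and -0.52 within session 2. The rise in DR5 was not called with only the compared groups in the fit (adjusted p = 0.114).

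The first comparison asks which genes depend on HDA6 in watered plants. At day 0, genes that were dim in DR5 and bright in axe1-5 gave the largest rises. AT1G58025, a bromodomain protein gene, was higher by 12.94 ± 0.72 (log2, n = 3) but was well above background on 1 of the 3 DR5 arrays. AT4G16215 was higher by 10.25 ± 0.60 (2 of 3 DR5 arrays), AT3G54730 by 9.09 ± 0.15 and AT5G26270 by 8.67 ± 0.59. AT5G01080 was at least 125-fold higher. The floral repressors MAF5, MAF4 and FLC were higher by 3.87 ± 0.69 (2 of 3 DR5 arrays), 2.94 ± 0.31 and 2.03 ± 0.37, and SOC1, which promotes flowering, was lower by -0.89 ± 0.21. In all, 656 genes were higher in axe1-5 and 143 lower, 489 and 63 of them by at least 2-fold. Of the 656, 410 were well above background on all 6 arrays, and 246 were not on all 3 DR5 arrays. Normexp background gave 421 genes higher and 130 lower. The largest falls were PORA (-3.19 ± 0.41), a chlorophyll synthesis gene, PXMT1 (-3.06 ± 0.65), the amino acid metabolism gene TAT3 (-2.98 ± 0.66), the floral identity gene AP1 (-2.96 ± 0.63) and the defence regulator WRKY38 (-2.62 ± 0.65). With slide as a block 662 genes were called, 568 higher and 94 lower, and FLC (adjusted p = 0.0523) and PXMT1 (adjusted p = 0.0667) were no longer among them. Of the 799 genes called, 797 kept their direction within session 1 and 798 within session 2, where part of this is built in.

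Of the 143 genes lower at day 0, 123 were well above background on all 6 arrays, but 4 of the 5 largest falls rest on dim levels. PXMT1, AP1 and WRKY38 were well above background on 1 of 3 axe1-5 arrays, and TAT3 on 2 of 3. With normexp background PXMT1, TAT3, AP1 and WRKY38 stood at -0.79, -1.73, -1.05 and -0.79 and were not called. They were not called either with only the day 0 arrays in the fit, nor without axe1-5 day 0 replicate 2, where the log2 folds were -2.61, -2.64, -2.51 and -1.94. TAT3 also lost its call without DR5 day 0 replicate 2 (-2.68), WRKY38 without any 1 of the DR5 day 0 arrays (-2.67 to -2.57), and SOC1 without DR5 day 0 replicate 2 (-0.76) or axe1-5 day 0 replicate 3 (-0.82).

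Among the fixed lists at day 0, floral organ markers had the lowest median in axe1-5 (-1.15) with the 75th percentile scaling. Of 10, 4 fell, 0 rose and 6 were not called, and 7 fell adjusted over the list alone (camera adjusted p = 3.83e-06, and adjusted p = 0.289 with an estimated correlation). LFY (-1.2 ± 0.24) and AG (-2.28 ± 0.50) were both lower in axe1-5, each with 1 of 3 axe1-5 arrays well above background (LFY also with 2 of 3 DR5 arrays), and neither was called with normexp background or with slide as a block. AG was also not called without axe1-5 day 0 replicate 1 (-2.01). Of 10 heat shock genes, 4 rose and 6 were not called, and 4 rose adjusted over the list alone (camera adjusted p = 0.000341, and adjusted p = 0.289 with an estimated correlation). HSP70 rose by 2.87 ± 0.48, its regulator HSFA2 by 2.64 ± 0.34, HSP90.1 by 2.29 ± 0.33 and HSP18.2 by 1.1 ± 0.19. Their calls held in every alternative run. The list median was 0.92, and 1.1 without the 3 members dim in both lines.

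Camera with the preset correlation placed several drought-linked and defence lists lower in axe1-5 at day 0, but few of their members were called and every such call was lost with an estimated correlation. Of 22 dehydrin and late embryogenesis abundant genes 2 fell, RD29A (-1.4 ± 0.29) and KIN2 (-0.97 ± 0.22), and 2 fell adjusted over the list alone (camera adjusted p = 0.000341, and adjusted p = 0.417 with an estimated correlation). Of 26 jasmonate genes 1 fell, AOS (-0.66 ± 0.13), and 2 adjusted over the list alone (camera adjusted p = 0.000132, and adjusted p = 0.289 with an estimated correlation). Of 14 abscisic acid phosphatases and transcription factors 1 fell, ABI5 (-0.86 ± 0.18), and 2 adjusted over the list alone (camera adjusted p = 0.00581, and adjusted p = 0.509 with an estimated correlation). Of 14 salicylic acid and defence genes 2 fell and 3 adjusted over the list alone (0.0347, and adjusted p = 0.53 with an estimated correlation). Of this list, NIMIN1 lost its call when any 1 of the 6 day 0 arrays was left out, and WRKY70 when any 1 of 5 was. Of 14 senescence genes 1 fell, also adjusted over the list alone (0.00333, and adjusted p = 0.289 with an estimated correlation). Of 10 circadian clock genes 1 fell and 2 adjusted over the list alone (0.00713, and adjusted p = 0.289 with an estimated correlation). The gene called, PRR5, was not called with slide as a block (limma adjusted p = 0.223), nor without any 1 of 5 day 0 arrays. The 27 photosynthesis genes (camera adjusted p = 0.00049, and adjusted p = 0.582 with an estimated correlation) and the 6 DREB genes (0.0413, and adjusted p = 0.346 with an estimated correlation) had 0 members called, and adjusted over the list alone 0 and 1 fell. RD29A, KIN2 and AOS were not called with only the day 0 arrays in the fit, and ABI5 was not called with normexp background. KIN2 was also not called without DR5 day 0 replicate 1 or 2 or axe1-5 day 0 replicate 2 or 3 (KIN2 adjusted p = 0.0526 to 0.101). The camera calls of the photosynthesis list ended with quantile normalization and with slide as a block. Those of the DREB list and the salicylic acid list ended with quantile normalization and with normexp background.

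Other lists at day 0 were not called by camera. Among 13 flowering time genes 3 rose and 1 fell, and 3 rose and 2 fell adjusted over the list alone, with a median of -0.13, a mean of 0.44 and an upward camera direction. Of 13 other histone deacetylases 2 rose, also adjusted over the list alone, with a median of -0.05, a mean of 0.24 and an upward direction. HDA7 was at least 1.48-fold higher, a call lost with normexp background, and HDA18 rose by 0.98 ± 0.21, a call lost with slide as a block. Of the 10 hypoxia genes 1 rose, and 1 rose and 1 fell adjusted over the list alone. The lists of abscisic acid metabolism, proline and raffinose metabolism, root markers, seed and embryo, reactive oxygen response, anthocyanin, expansins, cell cycle, aquaporins and auxin response had 0 members called, with 0 adjusted over the list alone. The 8 transposable element genes had 2 falls and 0 rises, with 2 falls adjusted over the list alone, and both falls were lost with normexp background.

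PDC1 (AT4G33070) answers a question on the acetate route, in which pyruvate decarboxylase and aldehyde dehydrogenase turn pyruvate into acetate. PDC1 was higher in axe1-5 at all 5 times, by 2.40 ± 0.21 at day 0 (limma adjusted p = 4.49e-08) and by 1.96, 1.84, 1.31 and 2.23 at days 6, 9, 12 and 15. ALDH2B7 (AT1G23800) was higher by 0.75, 0.94, 1.12 and 1.34 ± 0.19 at days 6 to 15, and its day 0 difference of 0.49 was not called (adjusted p = 0.23). PDC3 was higher by 2.16, 2.52 and 2.88 ± 0.43 at days 6, 9 and 12, with 1, 2 and 1 of 3 DR5 arrays well above background, and at least 2.72-fold at day 15. Its day 0 difference of 0.93 (2 of 3 DR5 arrays) was not called, but was 1.78 and called without DR5 day 0 replicate 2. PDC1 differed by 1.66 and 2.77 within sessions 1 and 2 at day 0 and by 2.29 and 2.2 at day 15. The 9-gene acetate list had 1 rise at day 0, also adjusted over the list alone (camera adjusted p = 0.0464, and adjusted p = 0.417 with an estimated correlation). That camera call ended with quantile normalization, normexp background and slide as a block. At day 15 it had 3 rises, also adjusted over the list alone (camera adjusted p = 0.335). The list comes from this study's own published work and is not independent evidence of its direction.

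Under drought most genes of the acetate list moved the same way in both lines. At day 15 PDC2 rose by 2.69 ± 0.16 in DR5 and 3.03 ± 0.16 in axe1-5, and PDC1 by 2.84 ± 0.21 and 2.67 ± 0.21. ADH1 rose by 6.06 ± 0.31 and 5.72 ± 0.31, but this list member is an alcohol dehydrogenase gene and not a step from pyruvate to acetate. ALDH2B7 rose by 2 ± 0.19 in DR5 and 2.86 ± 0.19 in axe1-5, and ALDH2B4 by 1.73 and 1.68. PDC3 fell in DR5, at least 2.86-fold, and stood at -1 ± 0.43 in axe1-5, where the call (adjusted p = 0.0403) was lost with normexp background, no filter, and slide or scan day in the model. It was also lost without axe1-5 day 0 replicate 1 or 3 or axe1-5 day 15 replicate 1, 2 or 3 (log2 folds from -1.05 to -0.90). ALDH2C4 fell in both lines (-0.82 ± 0.25 in DR5 and -1.32 ± 0.25 in axe1-5), and in DR5 the call was lost with only the compared groups in the fit (adjusted p = 0.111) and without DR5 day 15 replicate 1 (adjusted p = 0.0593). ACS and ACN1, which turn acetate into acetyl-CoA, were at -0.16 and 0.38 in DR5 and -0.29 and 0.32 in axe1-5, and of these only ACN1 in DR5 was called. That call was lost with quantile normalization (adjusted p = 0.0881), with only the compared groups in the fit (0.116), and without DR5 day 0 replicate 1 or 2 or DR5 day 15 replicate 2 or 3 (0.072 to 0.168). Of the 9 genes of the list, 6 rose and 2 fell in DR5 (camera adjusted p = 0.0726) and 5 rose and 2 fell in axe1-5 (0.037, and adjusted p = 0.259 with an estimated correlation), with the same counts adjusted over the list alone.

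**Figure D2:**
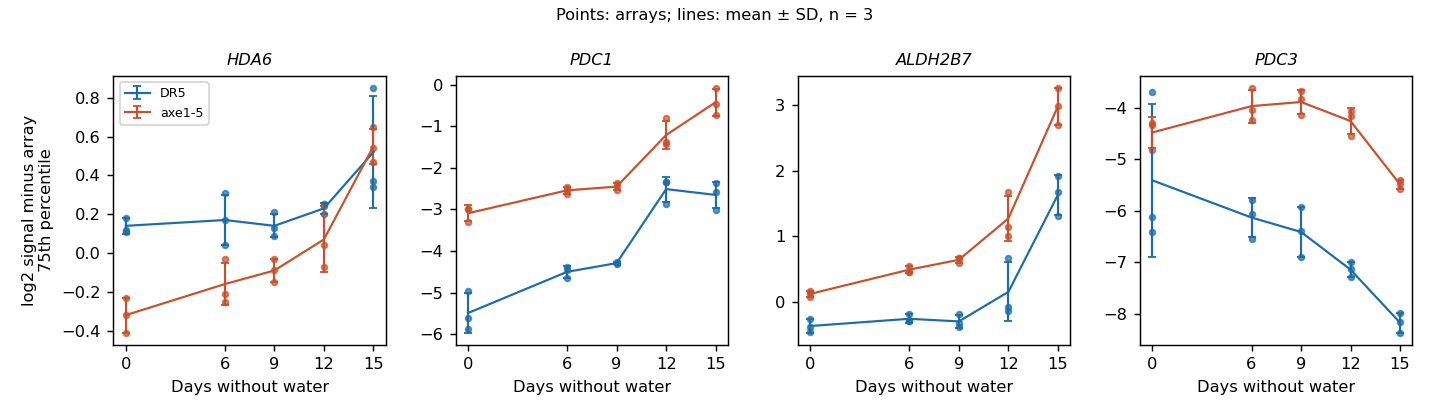
Levels of HDA6, PDC1, ALDH2B7 and PDC3 (log2 intensity relative to the array's 75th percentile, y axis) by days without water (x axis), with a point per array and the mean with its SD (n = 3). PDC1 in axe1-5 lies above DR5 at each time, from -3.09 against -5.49 at day 0 to -0.42 against -2.65 at day 15.

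The drought series of each line asks which genes change from day 0 as soil dries. No watered plants of the later days were sampled, so effects of age and harvest date cannot be told apart from drought. In DR5 at day 15 the largest rises were genes not well above background on any watered array. LEA7 rose at least 13030-fold, the membrane protein gene TSPO at least 8918-fold, AT3G17520 at least 8633-fold, AT5G66780 at least 2502-fold and AT2G42560 at least 1790-fold. The largest falls were AT3G16670 (at least 1793-fold), the thionin gene AT1G66100 (at least 1369-fold), AT1G31690 (at least 224-fold), AT3G05730 (-11.78 ± 0.60) and the lectin gene AT5G03350 (-10.74 ± 0.50), the last 2 on 1 of 3 day 15 arrays well above background. The number of genes called grew from 3229 at day 6 (1546 rose, 1683 fell) to 8120 at day 9 (3778, 4342), 11038 at day 12 (5415, 5623) and 16130 at day 15 (8283, 7847). With slide as a block the counts were 3994, 9000, 11812 and 15982. With only the compared groups in the fit they were 5636, 10459, 11436 and 13369, a smaller growth than with the spread shared over all groups. Of the 16130 genes, 15838 kept their direction within session 1 and 16104 within session 2, where part of this is built in because the same arrays made the calls.

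In axe1-5 at day 15, LEA7 rose at least 14240-fold, TSPO at least 9480-fold and AT3G17520 at least 9226-fold. The lipid transfer protein genes LTP4 and LTP3 rose by 15.11 ± 1.03 and 12.86 ± 0.83, on 1 of 3 watered arrays well above background. AT3G05730 and AT1G66100 fell at least 3031-fold and 1212-fold, and AT3G16670, AT1G22690 and AT1G06830 fell (-10.78, -10.53 and -9.52), on 1, 2 and 1 of 3 day 15 arrays. The counts were 2721 at day 6 (1473 rose, 1248 fell), 8063 at day 9 (3674, 4389), 10460 at day 12 (4949, 5511) and 14954 at day 15 (7564, 7390). With slide as a block they were 2557, 8476, 8384 and 13521. Of the 14954 genes, 14843 and 14936 kept their direction within sessions 1 and 2, where part of this is built in because the same arrays made the calls. With only the compared groups in the fit, the counts in axe1-5 were 6292, 10664, 11173 and 13645. In that fit DR5 did not have the larger count at day 15 (13369).

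**Figure D3:**
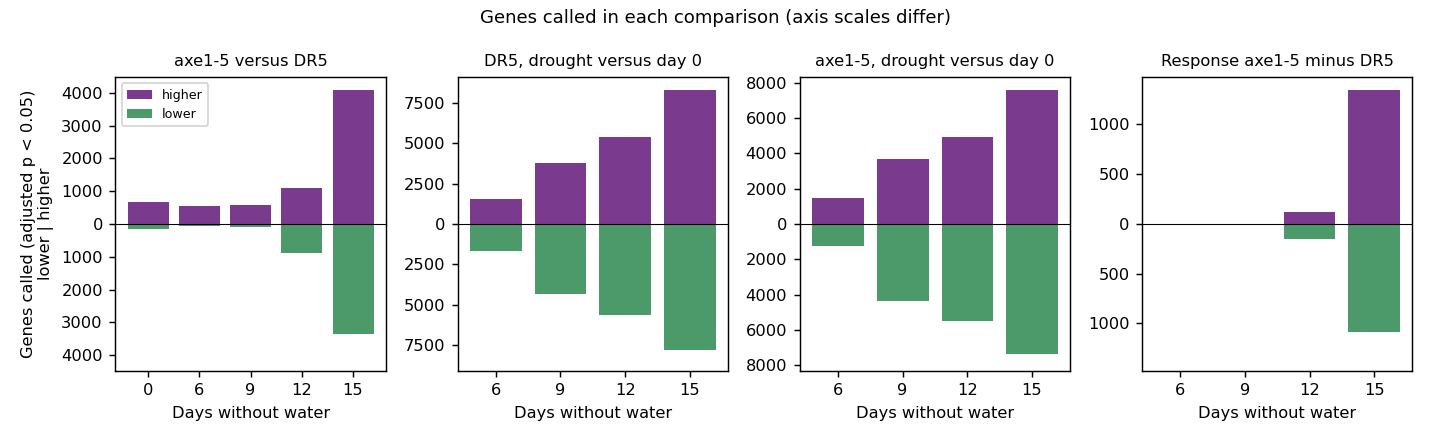
Number of genes called (y axis, with a scale of its own in each panel) by day, with genes higher drawn upward and genes lower drawn downward, for drought in DR5, drought in axe1-5, axe1-5 against DR5, and the difference of the responses. DR5 drought counts, with the spread shared over all groups, grow from 3229 at day 6 to 16130 at day 15.

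Hormone and protection genes rose in both lines at day 15. Here and in the paragraphs on day 15 lists that follow, values in brackets after a list are camera's adjusted p. They belong to the whole list, not to the gene named. Camera called the lists only with the preset correlation, and every call was lost with an estimated one (adjusted p = 0.306 to 0.405 in DR5 and 0.163 to 0.339 in axe1-5). Of 14 abscisic acid phosphatases and transcription factors 14 rose in DR5 and 13 in axe1-5, where 1 gave no test value. HAI1 rose by 10.01 ± 0.46 and 9.40 ± 0.46 (camera adjusted p = 1.73e-06 and 1.81e-07). Of 22 dehydrin and late embryogenesis abundant genes 21 rose in DR5 and 22 in axe1-5, LEA4-5 at least 1320-fold and 1674-fold (1.54e-09 and 5.13e-12). Of 9 proline and raffinose genes 7 rose in each line, 1 fell in DR5 and 2 in axe1-5, and the proline synthesis gene P5CS1 rose by 4.17 ± 0.33 and 5.24 ± 0.33 (0.0281 and 0.0078). Of 6 DREB genes 4 and 5 rose, DREB2A by 7.31 ± 0.32 and 6.44 ± 0.32 (0.0246 and 0.00207). Of 9 abscisic acid metabolism genes 6 rose and 2 fell in each line, and NCED3 rose by 3.75 ± 0.28 and 4.26 ± 0.28. This list was not called in either line (camera adjusted p = 0.0754 and 0.0604). Of 26 jasmonate genes 18 rose and 5 fell in DR5 and 21 rose and 2 fell in axe1-5, JAZ7 by 5.98 ± 0.46 and 5.14 ± 0.46 (0.0104 and 8.61e-05). Of 10 heat shock genes 8 and 7 rose, HSP21 at least 73-fold and 246-fold (0.00324 and 0.0135). Of 15 anthocyanin genes 13 rose and 1 fell in each line, DFR by 3.69 ± 0.69 and 5.62 ± 0.69 (0.00624 and 7.96e-05). Of 14 senescence genes 12 rose and 1 fell in each line, SAG13 by 8.69 ± 0.50 and 8.65 ± 0.50, the latter on 2 of 3 watered arrays (0.000183 and 4.32e-05).

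Growth and photosynthesis genes fell in both lines at day 15. Of 27 photosynthesis genes 26 fell in each, LHCB2.3 to -6.31 ± 0.34 in DR5 and -5.94 ± 0.34 in axe1-5 (camera adjusted p = 2.45e-08 and 2.43e-07). All 15 cell cycle genes fell, with medians of -3.58 and -3.97 (1.73e-06 and 1.81e-07), as did all 9 expansins, EXPA1 to -3.12 ± 0.31 and -4.23 ± 0.31 (0.00452 and 0.00142). Of 17 aquaporins 14 fell and 2 rose in DR5 and 15 fell and 2 rose in axe1-5, with medians of -2.19 and -2.8 (0.00043 and 8.61e-05). Of 15 auxin response genes 10 fell and 2 rose in DR5 and 9 fell in axe1-5, SAUR15 to -4.03 ± 0.48 and -3.47 ± 0.48. This list was not called in DR5 (camera adjusted p = 0.0726) and was called in axe1-5 (0.0215). The 10 floral organ markers all rose, PI by 5.80 ± 0.42 and 4.08 ± 0.42 (0.000804 and 0.000118). For every list called by camera at day 15 the call was lost with an estimated correlation, at an adjusted p = 0.306 to 0.405 with an estimated correlation in DR5 and 0.163 to 0.339 in axe1-5.

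The remaining lists were mixed at day 15 and not called by camera. Of 10 hypoxia genes 6 rose and 3 fell in DR5 and 5 rose and 2 fell in axe1-5, with the sucrose synthase gene SUS1 up by 5.16 ± 0.28 and 4.82 ± 0.28 (camera adjusted p = 0.135 and 0.0711). Of 10 clock genes 6 rose and 3 fell in each line, ELF4 by 6.33 ± 0.22 and 5.29 ± 0.22 (0.135 and 0.138). Of 10 reactive oxygen genes 7 rose in each line and 1 and 2 fell, ZAT10 by 5.59 ± 0.61 and 5.41 ± 0.61 (0.136 and 0.138). Of 14 salicylic acid and defence genes 5 rose and 8 fell in DR5 and 3 rose and 3 fell in axe1-5 (0.453 and 0.577), with medians of -0.72 and -0.16, means of 0.62 and 0.22 and a downward direction. Of 13 flowering time genes 3 rose and 5 fell in DR5 and 1 rose and 2 fell in axe1-5 (0.997 and 0.818), where the DR5 median of -0.49 had a mean of 0.46 and a downward direction. Of 13 other histone deacetylases 3 rose and 5 fell in each line (0.485 and 0.717), and in axe1-5 the median of 0.08 had a mean of -0.13 and a downward direction. Of 7 root markers 1 rose and 4 fell in DR5 and 5 fell in axe1-5 (0.381 and 0.138). Of 5 seed and embryo genes 4 and 3 rose (0.0778 and 0.27), and their medians of 3.38 and 1.62 became 1.86 and 0.38 with dim genes at their bound. Of 8 transposable element genes 5 rose and 2 fell in DR5 and 4 rose and 3 fell in axe1-5 (0.287 and 0.576), with medians of 2.05 and 1.77 that became 1.28 and 1.05. Counts adjusted over the list alone were the same in every list at day 15 of either line except heat shock in DR5 (9 rises) and transposable element genes in axe1-5 (5 rises). With slide as a block and within each session every list median kept its sign in DR5. In axe1-5 those of the salicylic acid, flowering time and histone deacetylase lists did not.

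**Figure D4:**
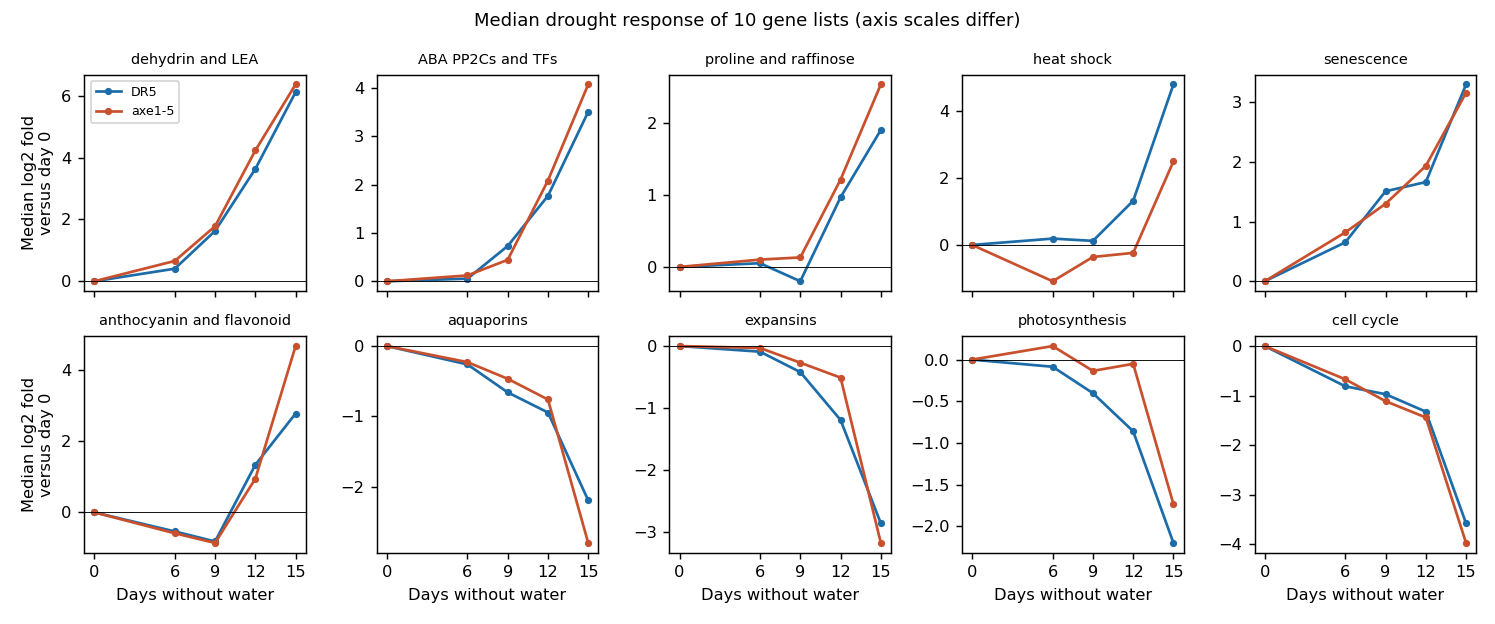
Median log2 fold against day 0 (y axis) of 10 gene lists by days without water (x axis) in DR5 and axe1-5. At day 15 the dehydrin list stands at 6.11 in DR5 and 6.37 in axe1-5, and the cell cycle list at -3.58 and -3.97.

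The responses of the lines were compared gene by gene, with no array shared between them. Folds against day 0 correlated across genes, which are not independent replicates, at r = 0.784 at day 6, 0.899 at day 9, 0.848 at day 12 and 0.905 at day 15. The slope of axe1-5 on DR5 through the origin was 0.749, 0.862, 0.715 and 0.792, and noise in the DR5 folds lowers such a slope. The SD of the folds was 0.605, 1.001, 1.352 and 2.267 in DR5 and 0.579, 0.961, 1.146 and 1.991 in axe1-5. At day 15, 6556 genes rose and 6436 fell in both lines, against 2979 and 2757 for independent lists, and 145 were called in opposite directions. In both lines, genes that changed the same way at all 4 drought days numbered 1065 rises and 1198 falls in DR5 and 1071 rises and 905 falls in axe1-5. With no filter on dim probes r was 0.65 at day 6 and 0.849 at day 9, and with normexp background 0.851 and 0.943.

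The lines were then compared at each drought day. At day 15 FT, which encodes a mobile flowering signal, was lower in axe1-5 by -6.46 ± 0.68 (2 of 3 axe1-5 arrays well above background), while FLC was higher by 2.94 ± 0.37. AT1G58025 was at least 3797-fold higher, AT5G01080 at least 204-fold, AT4G07965 at least 178-fold, AT5G41660 at least 167-fold, and AT5G26270 higher by 9.48 ± 0.59 (2 of 3 DR5 arrays). The largest falls were AT4G15750 (-9.57 ± 0.71), AT2G38900 (-8.98 ± 0.67) and AT5G47350 (-8.05 ± 0.72), on 2, 1 and 2 of 3 axe1-5 arrays, AT2G30810 (at least 71-fold) and EXPA21 (at least 55.4-fold). ALD1, a defence gene, was at least 8.02-fold lower, and HDA7 at least 3.77-fold higher. Of 15 anthocyanin genes 12 rose, also adjusted over the list alone (camera adjusted p = 0.0142, and adjusted p = 0.879 with an estimated correlation). UF3GT, TT19, PAP2 and LDOX of this list lost their calls without DR5 day 15 replicate 2, the array that stood apart. Of 10 floral organ markers 6 fell and 7 adjusted over the list alone (0.0264, and adjusted p = 0.879 with an estimated correlation), a camera call lost with slide as a block. Salicylic acid and defence genes split, with 5 rises and 5 falls among 14, also adjusted over the list alone (0.968), a median of 0.19, a mean of -0.71 and a downward direction. The medians within sessions 1 and 2 were 2.31 and 1.03 for anthocyanin genes and -0.64 and -1.57 for floral markers.

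Genes called between the lines numbered 628 at day 6 (558 higher and 70 lower in axe1-5), 654 at day 9 (573, 81), 1995 at day 12 (1099, 896) and 7417 at day 15 (4068, 3349). With slide as a block they were 543, 535, 623 and 3615. With only the compared groups in the fit they were 1241, 864, 1136 and 701, so the larger count at day 15 holds only where the spread is shared over all groups. Without DR5 day 15 replicate 2 the day 15 count was 5956. With normexp background day 6 gave 362 genes and day 12 gave 1273 higher and 668 lower. Leaving out 1 array moved the day 12 count to as few as 1140, and to 1281 without DR5 day 12 replicate 2. At day 12 slide as a block left 533 genes higher and 90 lower. Of the 7417 genes, 7335 and 7402 kept their direction within sessions 1 and 2, where part of this is built in because the same arrays made the calls. Over all genes the differences correlated between the sessions at r = 0.549. In the mean over the 5 times 5791 genes were called, 3077 higher and 2714 lower. This balance depends on the method, with 2960 higher and 3149 lower under quantile normalization and 1415 and 401 with slide as a block. All 10 floral organ markers fell in that mean, also adjusted over the list alone (median -1.33, camera adjusted p = 3.1e-07, and adjusted p = 0.434 with an estimated correlation). Their median was -0.45 with slide as a block and -0.82 with normexp background.

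The differences of watered plants were followed into drought. Of the 656 genes higher in axe1-5 at day 0, 460, 435, 433 and 434 were higher at days 6, 9, 12 and 15, where independent lists would share 17, 17.9, 34.3 and 127. Of the 143 lower at day 0, 32, 26, 21 and 44 were lower later, against 0.476, 0.551, 6.09 and 22.8. Called in the opposite direction were 0, 0, 7 and 45 of the 799, and the correlation across genes with the day 0 differences fell from 0.762 at day 6 to 0.365 at day 15. MAF5 was higher by 3.18, 2.89, 3.70 and 3.09 at the drought days, with 2 of 3 DR5 arrays well above background at days 6 and 15. At all 5 times 301 genes were higher and 8 lower. The genes changed the same way at day 0 and at days 6, 9, 12 and 15 numbered 492, 461, 454 and 478, and 270, 301 and 306 at days 6, 9 and 15 with normexp background.

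The last comparison tests whether the lines responded to drought differently. HSFA2, HSP70 and HSP90.1 rose less in axe1-5 by day 15 (differences of -3.80 ± 0.49, -3.20 ± 0.68 and -3.10 ± 0.50), while the heat shock list was not called. These 3 genes were already higher in watered axe1-5, by 2.64, 2.87 and 2.29. That day 0 difference enters each value with its sign reversed and makes up much of it. The cold and drought gene KIN2 and the flavonoid gene CHS rose more in axe1-5, by 1.48 ± 0.32 and 2.08 ± 0.48. GOLS3 fell in both lines, but less in axe1-5 (a difference of 2.67 ± 0.56). The jasmonate synthesis gene AOS and the floral repressor SVP fell in DR5 and were not called in axe1-5 (differences of 1.19 ± 0.18 and 0.89 ± 0.15). KIN2 and AOS were lower in axe1-5 at day 0, which enters their values in the same way. FT rose in DR5 and was not called in axe1-5 (-5.51 ± 0.96, on 2 of 3 axe1-5 day 15 arrays well above background). The largest fitted positive differences (axe1-5 minus DR5) were NUDT24 (5.30 ± 1.07), XTH31 (5.26 ± 0.91), AT4G16270 (4.76 ± 1.26), UMAMIT36 (4.28 ± 0.86) and WRKY54 (4.13 ± 0.59). The largest fitted negative ones were AT4G15750 (-10.17 ± 1.01), AT2G38900 (-9.04 ± 0.95), AT5G47350 (-7.99 ± 1.02), GAD3 (-7.85 ± 0.70) and AT2G30810 (-7.80 ± 0.71). NUDT24, AT4G16270 and these 5 had 0 arrays well above background in at least 1 of the 4 groups, so neither the size of their difference nor their rank is reliable. XTH31, UMAMIT36 and WRKY54 had 2 of 3 DR5 day 15 arrays above it. Of the 49 calls among the 58 genes looked up by name, 34 were lost with slide as a block, among them SVP, HSP70 (adjusted p = 0.0516), GOLS3 (0.0771), FT (0.146), AT5G47350 (0.0507), UMAMIT36 (0.0675) and AT4G16270 (0.158). Leaving out 1 array at a time ended 21 of the 49. With only the compared groups in the fit 33 were lost, among them FT, CHS, XTH31, UMAMIT36 and AT4G16270, which was also lost without DR5 day 0 replicate 2 (4.09).

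By limma 0 genes differed in response at day 6 (303 at an unadjusted p under 0.05), 1 at day 9 (534), 274 at day 12 (2662) and 2427 at day 15 (5973). The 303 and 534 are fewer than a share of 0.05 of the 21014 and 21012 genes tested, so they are no sign of differences. The shared spread exceeded that of the compared groups alone at day 6 (median SE 0.289 against 0.172). At day 15 it was smaller (0.289 against 0.341), so the counts of these days are not directly comparable. The fold was higher in axe1-5 for 122 and lower for 152 at day 12, and for 1342 and 1085 at day 15, where a higher fold can be a smaller fall. With slide as a block the counts were 0, 0, 30 and 406, and with only the compared groups in the fit 1, 6, 574 and 473. Of the 2427 genes 1214 were called the same way in both lines, 308 with a larger and 906 with a smaller response in axe1-5. Within sessions 1 and 2, 2422 and 2421 kept their direction, where part of this is built in because the same arrays made the calls. Over all genes the differences of response at day 15 correlated between the sessions at r = 0.471. ALDH2B7 rose more in axe1-5 by 0.85 ± 0.26 (adjusted p = 0.0393), a call lost with slide as a block (0.400) and with only the compared groups in the fit (0.132). That call was also lost without any 1 of the DR5 day 0 or axe1-5 day 0 arrays, DR5 day 15 replicate 1, or axe1-5 day 15 replicate 1 or 3 (log2 differences from 0.69 to 0.90). PDC1 differed by -0.17 ± 0.30 and was not called, but stood at 0.79 and was called with normexp background. In the acetate list 1 of 9 had a higher fold in axe1-5, and 2 adjusted over the list alone (camera adjusted p = 0.91). Of 27 photosynthesis genes 3 fell less in axe1-5, also adjusted over the list alone (0.00272, and adjusted p = 0.95 with an estimated correlation), a camera call lost with quantile normalization and slide as a block. Among these, LHCB5 lost its call without any 1 of 8 arrays and LHCA2 without any 1 of 7. Of 15 anthocyanin genes 2 rose more, also adjusted over the list alone (0.00279, and adjusted p = 0.95 with an estimated correlation). Of 10 heat shock genes 4 had a lower fold, also adjusted over the list alone (0.224). The list medians within sessions 1 and 2 were 1.15 and 0.19 for photosynthesis, 3.44 and 0.51 for anthocyanin and -3.08 and -0.65 for heat shock genes.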

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

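Genes whose drought response differed between the lines come from a test of the difference planned before the data were examined. All tests of explanations below were chosen after the results were seen.

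The differences of response numbered 1 gene at day 9, 274 at day 12 and 2427 at day 15. The lines were relabelled in 100 splits of the 12 arrays of each comparison. At day 6, where 0 genes were called, 100 of 100 splits gave as many, as any split must, with up to 1453. At day 9, 9 of 100 splits gave at least 1 gene, with up to 292 in the others. At day 12, 12 of 100 gave at least 274, with up to 1643. At day 15, 5 of 100 gave at least 2427, with up to 4663. Splits that call several times the real count point to a structure of the samples: relabelling arrays between the lines brings the difference between the lines into the comparison. The highest splits at days 6, 12 and 15 relabelled all 6 drought arrays and 0 day 0 arrays. These splits therefore leave chance open: they neither exclude it nor count for it.

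Values here are the fold against day 0 in axe1-5 minus that in DR5 (log2), so a positive value can be a larger rise or a smaller fall. Stress and hormone genes with a positive value at day 15 were COR15B (2.35), KIN2 (1.48), RD22 (0.90), GOLS3 (2.67), GOLS1 (1.07), CBF3 (2.29), ABF1 (1), CORI3 (1.68), AOS (1.19), OPR3 (0.98), PAD4 (1.73), SUS4 (1.02), ALDH2B7 (0.85), RNS1 (2.36) and FSD1 (0.93). Photosynthesis, pigment, growth and other genes with a positive value were LHCB4.2 (1.25), LHCB5 (1.1), LHCA2 (0.87), CHS (2.08), UGT78D2 (1.05), EXPA5 (0.92), SVP (0.89), AP1 (2.79), LFY (1.2), HDA2 (0.81), NUDT24 (5.30), XTH31 (5.26), AT4G16270 (4.76), UMAMIT36 (4.28) and WRKY54 (4.13). Heat shock genes with a negative value were HSFA2 (-3.80), HSP70 (-3.20), HSP90.1 (-3.10) and HSP101 (-2.10). Others with a negative value were the defence genes PR1 (-3.91), ALD1 (-3.77) and FMO1 (-3.57), FT (-5.51), DIN10 (-2.86), CASP2 (-1.72), LEC1 (-3.41), OLEO2 (-2.50), ELF4 (-1.05), AT2G26490 (-3.74), AT4G15750 (-10.17), AT2G38900 (-9.04), AT5G47350 (-7.99), GAD3 (-7.85) and AT2G30810 (-7.80). Of these 49 genes, 29 were well above background on all arrays of the 4 groups. NUDT24, AT4G16270, OLEO2, FMO1, AT2G26490, ALD1, PR1, AT2G30810, GAD3, AT5G47350, AT2G38900 and AT4G15750 had a group with 0 such arrays, so their sizes are not reliable. XTH31, UMAMIT36, WRKY54, AP1, RNS1, LFY, LEC1 and FT had a group with 1 or 2, so theirs are uncertain. Of the 49 calls, 34 were lost with slide as a block, 33 with only the compared groups in the fit and 21 when 1 array or another was left out. The calls of 10 genes were lost in no alternative that tested them, and of these only KIN2, AOS, HSFA2 and HSP90.1 were also above background on all arrays. At day 0 KIN2 and AOS were lower in axe1-5, and HSFA2 and HSP90.1 higher. The difference of responses holds these day 0 differences with the sign reversed.

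Probes outside the gene counts also gave signals above the parental line. Of 1673 chromosome interval probes tested, 70 were higher in axe1-5 at day 0 and 208 in the mean over the 5 times, against 5 and 134 lower. Of the probes for other transcripts, 34 of 1033 were higher at day 0 and 98 of 1032 in the mean, against 6 and 94 lower.

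The first pattern is the excess of genes higher over genes lower in axe1-5 at days 0, 6 and 9 (656 against 143 at day 0). Among genes well above background on all 6 arrays compared, the lowest ratio over the 3 days was 3.33, which argues against probes near background as the cause. It was 3.08 over quantile normalization and normexp background, and 6.04 with slide as a block, which argue against the scaling of the arrays and against the slide. What stays open as a hypothesis is that loss of HDA6 may release genes that it keeps silent, and the design has no second allele or complemented line to test it.

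The second pattern is that more genes were called between the lines at day 15 (7417) than before. Without DR5 day 15 replicate 2 the count was 5956, so that array alone is not the cause. With the spread of the compared groups alone it was 701 against 1078 at day 0, so the growth of the count may come from a replicate spread pooled over the groups. The covariance of the folds between the scan sessions was 3.05 times larger at day 15 than at day 0 (0.793 against 0.26), which argues against the spread as the source of the larger differences themselves. Axe1-5 lagging behind in the same response stays open: 7.58% of the 2427 genes moved further in axe1-5 while DR5 still moved. That share lies between the cut-offs set for either outcome after the results were seen. The line difference at day 15 correlated at r = -0.21 with the DR5 response at day 12. The line difference at day 12 correlated at r = -0.43 with the DR5 response at day 15. Negative values go with a smaller or a later response in axe1-5 and do not separate these.

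The third pattern is the higher level of HSP70, HSFA2, HSP90.1 and HSP18.2 in axe1-5 at day 0. The smallest gap between the lowest axe1-5 and the highest DR5 array was 0.74 (log2), which argues against a single array for these 4 genes. Part of this gap is built in because the same arrays made the calls. The median of the 4 genes was 2.50 with slide as a block against 2.46 without, which argues against the slide. The hour of harvest cannot be told apart from the lines: the labels give no hour, and 1 of 10 clock genes was called. That gene, PRR5, lost its call with slide as a block (limma adjusted p = 0.223) and without any 1 of 5 day 0 arrays. The heat shock list median between the lines was 0.92 at day 0 and -0.07, 0.17, -0.47 and -0.38 at days 6, 9, 12 and 15. With dim members left out or at their bound it was 1.1, 0.58, -0.04, -0.47 and -0.38. The list was thus not higher in axe1-5 at days 12 and 15. A biological effect of HDA6 on heat shock genes may explain the day 0 level but was not tested.

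Within pairs of groups, 6 arrays make 10 splits, too few for a share under 0.05, and 1 of 10, the real split, gave as many genes in each comparison. For axe1-5 against DR5 the real and highest other counts were 799 and 0 at day 0, 628 and 0 at day 6, 654 and 0 at day 9, 1995 and 97 at day 12 and 7417 and 4405 at day 15. The splits with 97 and 4405 put both session 1 arrays on the same side, as several of the 10 splits do whatever the data. They also part DR5 day 12 replicate 2 or DR5 day 15 replicate 2, which stood apart, from its group. The scan session and the single array therefore cannot be told apart here. Within sessions 1 and 2, 1993 and 1993 of 1995 genes kept their direction at day 12 and 7335 and 7402 of 7417 at day 15, where part of this is built in. For drought in DR5 they were 3229 and 0, 8120 and 1, 11038 and 2, and 16130 and 5, and in axe1-5 2721 and 0, 8063 and 0, 10460 and 1, and 14954 and 7. Of these the splits with 2 at day 12 in DR5 and with 7 at day 15 in axe1-5 also put both session 1 arrays on the same side. In these comparisons 10984 and 11028 of 11038 genes and 14843 and 14936 of 14954 kept their direction within sessions 1 and 2. For the mean over the 5 times, 1 of 100 splits, the real one, gave 5791 genes, with 2683 the highest of the others. That share is the smallest these splits can give and argues against chance, but the splits do not address the slide.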

How the results depend on the processing

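The fits with scan session as a block, without DR5 day 15 replicate 2 and without the day 15 arrays were chosen after seeing the data. Counts are given where they moved by over 1.5 times, and the cause was not tested unless stated. Counts of genes kept within 1.5 times under quantile normalization, the mean over probes and the authors' table in all 18 comparisons.

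Normexp background gave 362 genes between the lines at day 6, 3 genes for the difference of responses at day 9, r = 0.851 and 0.943 between the responses at days 6 and 9, and 270, 301 and 306 genes called in the same direction at day 0 and at days 6, 9 and 15. It turned PDC1 in the difference of responses at day 15 from -0.17 to 0.79 (SE 0.25, adjusted p = 0.0304). With no filter on dim probes the difference at day 9 had 0 genes, and r was 0.65 and 0.849.

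Slide as a fixed block gave counts between the lines of 623 at day 12, 3615 at day 15 and 1816 in the mean, and for the difference of responses of 0 at day 9, 30 at day 12 and 406 at day 15. The slide terms use degrees of freedom, and no slide holds both lines at the same day, so the line difference is also less precise (median SE 0.252 against 0.205 at day 12). At day 9 the difference had 3 genes with slide as a random block, 2 with scan day and 2 with scan session as a block, and at day 12 it had 423 with scan session.

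With only the compared groups in the fit, each count rests on fewer arrays and its own spread. Between the lines it gave 1241 genes at day 6, 1136 at day 12 and 701 at day 15. At day 6 of drought it gave 5636 in DR5 and 6292 in axe1-5. The differences of response were 1, 6, 574 and 473 at days 6, 9, 12 and 15.

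Without DR5 day 15 replicate 2, 944 genes were called between the lines at day 6 and 3076 at day 12, 5241 and 4479 at day 6 of drought in DR5 and axe1-5, and 1, 6 and 777 for the difference at days 6, 9 and 12. Without the day 15 arrays, whose spread was the largest, the counts between the lines were 1369, 1168, 1169 and 3839 at days 0, 6, 9 and 12. At day 6 of drought they were 6302 in DR5 and 5481 in axe1-5, and for the difference 1, 4 and 1434 at days 6, 9 and 12.

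With 1 array left out at a time, the lowest and highest counts were 1140 and 2078 between the lines at day 12, 1997 and 2660 at day 6 of drought in DR5, and 1530 and 2233 in axe1-5. The difference of responses gave 0 to 1 gene at day 6, 0 to 2 at day 9, 62 to 485 at day 12 and 1541 to 3935 at day 15. These fits have fewer arrays.

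The replicate numbers were set as a block although they showed no clear pairing of samples. Of 135 same-numbered pairs 65 correlated above 0.1, the lowest at -0.45, and 12 of 30 arrays correlated best with an array of their number. The mean correlation was 0.093 for the same number and -0.046 for other numbers, against 0.184 for the same slide. A weak pairing is therefore not excluded. The block changed no count by over 1.5 times: 812 genes were called between the lines at day 0, 2201 at day 12 and 7721 at day 15, and 2767 for the difference at day 15. It took away the call of the acetate list at day 0.

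Calls of single genes looked up by name were lost most at day 15 between the lines and in the difference of responses. Of 86 and 49 calls there, 65 and 33 were lost with only the compared groups in the fit, 33 and 34 with slide as a block, 34 and 21 when 1 array or another was left out, and 6 and 9 with normexp background. Of 35 calls at day 0, these settings took 10, 10, 14 and 13. Of 112 calls for drought in DR5 they took 5, 1, 5 and 4, and of 107 in axe1-5 1, 2, 3 and 4. Over all settings 13 calls at day 0, 20 and 10 of the 86 and 49, and 103 and 102 of those for drought were never lost. Of 125 list tests between the lines at days 0 and 15, for drought at day 15 in each line and for the difference at day 15, 43 were called with a preset correlation and 0 with an estimated one. Elsewhere 1 list stayed called at days 6 and 9 in DR5 each, and 3 at days 6, 9 and 12 in axe1-5 each. Genes dim in a group are limited by signal over background: their folds are bounds where 0 of 3 arrays were above it, and otherwise, and in all differences of responses, uncertain fitted values.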

Other observations

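The tests in this part were chosen after the results were seen. In all, 301 genes were higher in axe1-5 at all 5 times and 8 were lower. Of 17 description words tested by Fisher's exact test, hypothetical protein was attached to 57 of the 301 against 9.56 by proportion (adjusted p = 8.31e-27), F-box to 26 against 4.62 (1.1e-11) and DC1 domain to 9 against 0.744 (2.71e-07). Ulp1 protease stood at 3 against 0.2 (0.004), disease resistance protein at 8 against 2.26 (0.0069) and MADS-box at 4 against 0.644 (0.0109), while ribosomal protein was at 0 against 5.01 (0.0267). SDC, an F-box gene, was higher by 4.44 at day 0, at least 31.1-fold at day 6 and at least 29.1-fold at day 9, and by 2.83 at day 15. QQS was higher by 3.09 at day 0 and 2.06 at day 12 (± 0.17).

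Some of these genes are neighbours in the order of the tested loci, in which loci that were not tested are skipped. Of the 301 genes, 298 had a place in the order of loci, and they made 18 neighbouring pairs against a mean of 4.26 in 10000 random sets, with 13 the highest (permutation p = 1e-04, the smallest these sets can give). Sets matched on mean signal gave a mean of 4.45 and at most 16 pairs. Among the pairs were MAF4 with MAF5, QQS with AT3G30770 and AT5G35480 with MRU1. Some pairs are related genes, such as MAF4 with MAF5, and probes that read the transcript of a neighbour were not excluded for any pair.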
